A study of Homo sapiens with 6 samples.

How the data were processed

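Total RNA from ES-2 cells, an established human ovarian cancer cell line, was hybridised to 6 Affymetrix PrimeView arrays, 1-colour oligonucleotide arrays that measure each transcript with 1 or more probe sets. Per the labels, 3 arrays came from cells overexpressing CADM1 and 3 from control cells, which the series describes as mock controls. The titles, descriptions and genotype fields gave the groups, although the source names of 2 of the overexpression arrays read CADM2 and CADM3. The labels do not say that the arrays of a group came from separate cultures, so p-values measure the spread between these arrays, which may be technical, and they give no batch or date.

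The data were a single table of 49395 probe sets by 6 arrays. The deposited log2 values are credited to MAS5 by the authors, per the submitters' processing notes, which give no version or setting. These values were taken to be on a log2 scale, from their range of 2.15 to 14.33 and the near-identical medians, 6.18 to 6.20, of the 6 arrays. Their tight low end, with array minima of 2.15 to 2.23 and 25th percentiles of 4.28 to 4.34, looks more like a summary of the RMA type than MAS5, so the summary method stays unsettled, and with it what low values and the size of fold changes mean. The log base and the method of scaling between arrays are not given in the sources used here. No genome build was named, so no coordinates are printed. Detection calls and scanner files were not used here, so signal over background was not assessed and the number of arrays limits the precision.

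Probe sets were named from the platform annotation. Of the 49395 probe sets, 44988 named 1 gene, 1832 named several, 2473 named none and 102 were array controls. The gene number of 44967 of the 44988 matched the current gene table, which gave the symbols. Each gene was represented by the probe set with the highest mean over the 6 arrays among those naming 1 gene, and by a probe set of the _x_at type, which can match several transcripts, only where it had no other (601 genes). This left 18118 genes, of which 11737 had more than 1 probe set. No further normalization and no filter on dim probe sets was applied.

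The labelled groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend, group as the single term). Tests were two-sided with Benjamini-Hochberg adjustment over all genes, and a gene was called at an adjusted p under 0.05. Log2 fold changes are arrays labelled overexpression minus arrays labelled control. On simulated values for 18118 genes in this comparison, 48.5% of the genes changed by 0.25 on the log2 scale were recovered, 91.0% of those changed by 0.5 and 100% of those changed by 1, with 7 false calls among 17918 unchanged genes. The simulated noise was normal, set by each gene's own spread and independent between genes. These rates therefore do not cover noise that genes or arrays share.

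Gene lists were fixed before the data were examined, 33 for pathways and gene families and 6 for housekeeping genes and markers of cell types, with 798 of their 861 distinct genes measured. They were tested with limma's camera, which compares a list with all other genes, at the preset correlation of 0.01 between genes, and adjusted over the 33 lists, or over the other 6, by Benjamini-Hochberg. The 33 lists were tested again with an estimated correlation and with fry. The other listed genes, CADM2 among them, were not analysed here.

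The genes named were set by a rule written before the data were examined. It takes CADM1 and CADM3, then the 12 genes with the highest and the 12 with the lowest log2 fold change among called genes with no overlap between the groups and a level at or above the median of all probe sets in the higher group. It also takes up to 4 called members per list, or the 2 with the lowest p where none was called. Further members are given as values and were chosen after their values were seen. The alternatives were another normalization (quantile, median centring), an offset added on the linear scale, 2 filters on dim genes, the mean of all probe sets or each probe set alone, another variance model, array weights, the replicate number as a block, leaving out each array, other set tests and a plain t-test. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.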

Results

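Expression in ES-2 ovarian cancer cells was measured on 6 arrays, 3 labelled CADM1 overexpression and 3 labelled control. CADM1 is a cell adhesion molecule of the immunoglobulin superfamily, and the series set out to look for regulatory pathways linked to its tumour suppressor role. Array medians lay between 6.18 and 6.20 on the log2 scale, which was inferred from the values, and the method that summarised the probes is unsettled. The correlation between arrays over the 18118 genes, with 1 probe set each, ran from 0.998 to 0.999. The median SD within a group was 0.065.

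The first comparison asked how CADM1 itself differed between the labelled groups. The brightest CADM1 probe set, 11728805_a_at, was lower in the arrays labelled overexpression, at 8.14 ± 0.040 (SD, n = 3), than in the arrays labelled control, at 10.26 ± 0.030 (SD, n = 3). This is a log2 fold change of -2.12 ± 0.031 (SE), with the signal 4.34-fold higher in the arrays labelled control (limma, adjusted p = 5.42e-15). The direction is opposite to the labels and held in each of the 6 arrays. None of the other 5 CADM1 probe sets was called: their log2 fold changes were 0.04 for 11728806_a_at, 0.04 for 11741375_a_at, -0.01 for 11754473_a_at, 0.17 for 11757557_s_at and -0.06 for 11762680_s_at. All 5 were dimmer, averaging 6.95, 6.81, 5.73, 7.55 and 3.67 in that order, against 9.20 for the brightest. The median of all probe sets was 6.19, and without detection calls it is not known whether these 5 detect CADM1. The mean of all 6 CADM1 probe sets gave -0.32, still called. CADM3, named in the source name of 1 overexpression array, differed by 0.03 ± 0.076 (SE) at levels of 5.83 and 5.80 (limma, adjusted p = 0.916). Its dimmer probe sets were not called either. Of these, 11723741_a_at gave 0.24 without overlap between the groups (limma, adjusted p = 0.184 over all probe sets), and 11723742_a_at gave 0.13. The groups are named by their labels throughout, every direction given is that of the labels, and the position of each probe set relative to the introduced sequence is not given in the sources used here.

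**Figure D1:**
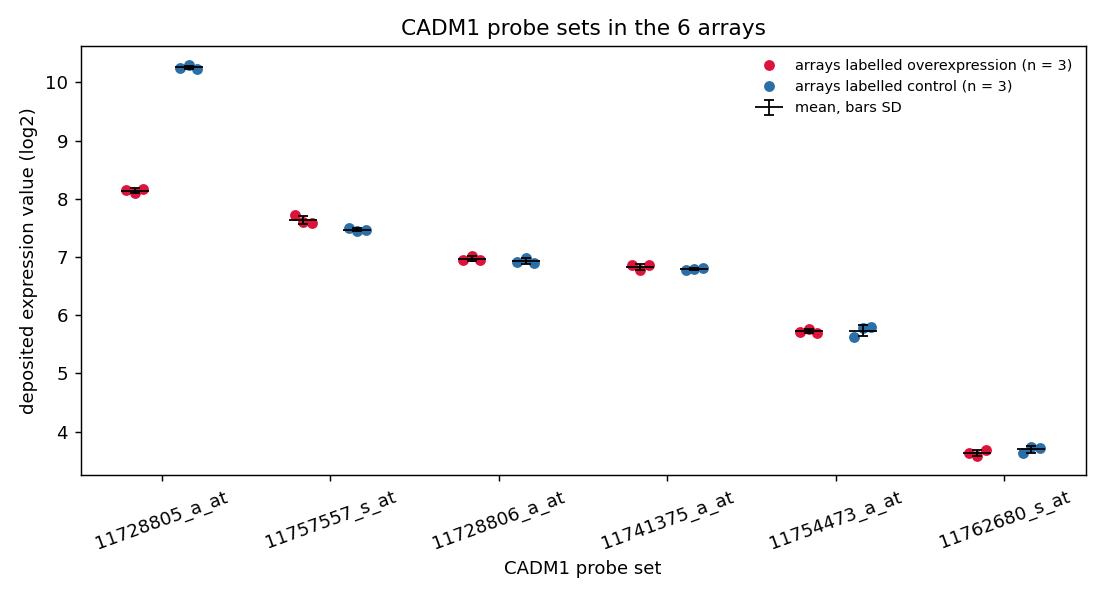
Deposited log2 expression value (vertical axis) of the 6 CADM1 probe sets (horizontal axis), with 1 point per array, 3 arrays per labelled group, and black bars for mean and SD. Probe set 11728805_a_at averaged 8.14 in the arrays labelled overexpression and 10.26 in the arrays labelled control, while the log2 fold changes of the other 5 lay between -0.06 and 0.17.

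Across the genome, and after CADM1, interferon-inducible genes led the genes that were lower in the arrays labelled overexpression. IFI27 had a log2 fold change of -1.78 ± 0.044 (SE) and a signal 3.44-fold higher in the arrays labelled control (limma, adjusted p = 5.06e-12), and its other, brighter probe set, of the _x_at type, fell by 2.17. IFI6 fell by 0.77 and TGM2, a protein cross-linking transglutaminase, fell by 0.62. IFITM1, an antiviral membrane protein, fell by 0.61, and UBE2L6, the conjugating enzyme for ISG15, fell by 0.54. SPOCK1, a matrix proteoglycan, fell by 0.41, C4BPA, a complement regulator, fell by the same amount. LMNB1, the nuclear lamina protein lamin B1, fell by 0.37, TNNT1, a troponin, by 0.37, and MSMO1, an enzyme of cholesterol synthesis, by 0.36. TMEM67, a protein of the cilium, fell by 0.44, but its 7 probe sets did not share 1 sign. Another was called at 0.41, though it was dim, with means of 3.30 and 2.89.

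ABCA1, the membrane pump that exports cholesterol, rose in the arrays labelled overexpression, with a log2 fold change of 0.72 ± 0.052 (SE) (limma, adjusted p = 3.19e-06). Of its 3 probe sets 2 had this sign, and the other, at -0.17, averaged a dim 2.82 and was not called. OSGIN1, an oxidative stress-induced gene, rose by 0.43, EDN1, the precursor of the vasoconstrictor endothelin, by 0.34, and CLIP4 by 0.33. SLCO1C1, an organic anion transporter, rose by 0.33, ALPK2 by 0.31, CYP4F11, a cytochrome of fatty acid oxidation, by 0.30. HHIPL2 rose by 0.28, as did AHRR, the repressor of the aryl hydrocarbon receptor. KRTAP12-2 at 0.43 belongs to a family of close copies and TTC3P1 at 0.29 is a pseudogene of TTC3, so both may carry signal from related transcripts. RAP1A, a small GTPase, was called at 0.39 from 1 of its 4 probe sets, whose means of 14.22 and 13.83 lie near the top of the scale. The other 3 gave -0.02, -0.01 and -0.14 and were not called.

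In all, 392 of 18118 genes were called (limma), 174 higher and 218 lower in the arrays labelled overexpression, and 2 of them, CADM1 and IFI27, changed at least 2-fold. The median absolute log2 fold change of the called genes was 0.17, and at an unadjusted p under 0.05 there were 2523 genes. All 392 had groups that did not overlap, as did 18.3% of all genes against 10% by chance. Without a mean-variance trend 11 genes were called, every one of them named above. With the first or second overexpression array left out 116 and 226 were called, and without the first or second control array 142 and 189. ABCA1, CADM1, CLIP4, IFI27, IFI6, IFITM1, LMNB1, SPOCK1, TGM2 and UBE2L6 were called in each of the 17 fits at the gene level.

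**Figure D2:**
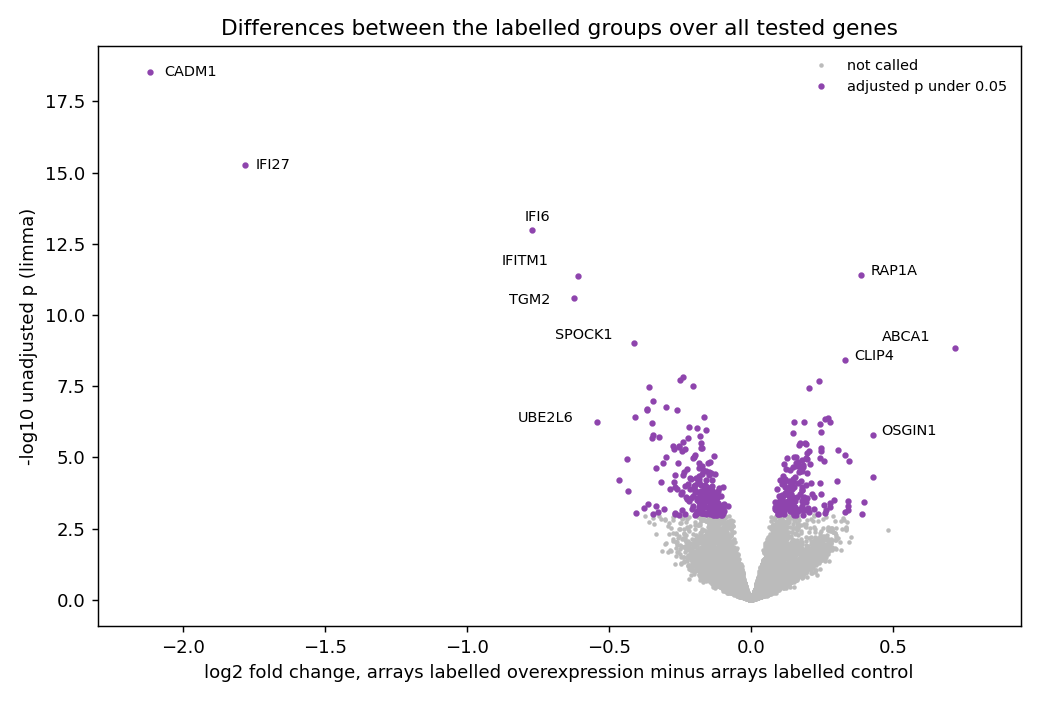
Log2 fold change of 18118 genes, arrays labelled overexpression minus arrays labelled control (horizontal axis), against -log10 of the unadjusted limma p (vertical axis), with 1 point per gene and called genes in purple. CADM1 at -2.12 and IFI27 at -1.78 stand apart from the other called genes, whose absolute log2 fold changes were at most 0.77.

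Interferon-stimulated genes, which act in antiviral defence, were lower as a group in the arrays labelled overexpression. Of 31 measured members, 11 fell and none rose (15 fell when adjusted over the list alone), with a median log2 fold change of -0.11 (camera, adjusted p = 2.27e-13; adjusted p = 0.0497 with an estimated correlation). Among those that fell were IFI27, IFI6, IFITM1 and OASL, the last by 0.34 (limma, adjusted p = 0.000113), and the RNA sensor RIGI fell by 0.33. OASL was read by 1 probe set, of the _x_at type. MX1, with levels of 4.49 and 4.47, gave 0.02 and IFIT1 gave -0.13, and neither was called. Among 13 genes of MHC class I and antigen processing, HLA-C fell by 0.11, although its probe sets may carry signal from other class I genes, and 2 fell when adjusted over the list alone (camera, adjusted p = 0.0247; adjusted p = 0.242 with an estimated correlation). That list lost its call with genes at or above the median level (adjusted p = 0.0675), without a trend (0.152), and without the first (0.0604) or second (0.0517) overexpression array or the second control array (0.119).

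Genes of the NRF2 response, which make glutathione and detoxify oxidants, were higher in the arrays labelled overexpression. Of 22 measured members 11 rose and none fell, and 17 rose and 1 fell when adjusted over the list alone (camera, adjusted p = 7.02e-19; adjusted p = 0.0172 with an estimated correlation). OSGIN1 rose by 0.43, SRXN1, which repairs oxidised peroxiredoxins, by 0.24 ± 0.021 (SE), and the glutathione enzymes GSR and GCLC by 0.18 each. AKR1C1, AKR1C2 and AKR1C3 rose too, but are close copies of each other whose signals may not be separate. Of 9 metallothioneins none was called over all genes and 1 fell when adjusted over the list alone; MT2A gave -0.06 and MT1X -0.10 (camera, adjusted p = 0.0938). The metallothionein list was called as lower without the first overexpression array (adjusted p = 0.0342).

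Targets of ERK signalling and genes of DNA replication were lower in the arrays labelled overexpression. Of 22 ERK targets 8 fell and none rose, and 12 fell when adjusted over the list alone (camera, adjusted p = 3.91e-09; adjusted p = 0.0497 with an estimated correlation). ETV5 fell by 0.35, the phosphatase gene DUSP5 by 0.27, PHLDA1, by 0.24, and ETV4, by 0.22. Of 32 replication genes 5 fell and none rose, and 14 fell when adjusted over the list alone (camera, adjusted p = 9.15e-10; adjusted p = 0.0497 with an estimated correlation). MCM10, a replication initiation factor, fell by 0.20, the nucleotide enzymes RRM2 and TK1 by 0.18 each, and the primase subunit PRIM1 by 0.14. Only 2 of the 4 RRM2 probe sets had that sign. The other 2 were dim, averaging 2.91 and 4.34, and were not called. None of 32 mitotic genes was called by either adjustment, with NUSAP1 at -0.09 and CDK1 at -0.06. The list was called as lower (camera, adjusted p = 0.0238; adjusted p = 0.226 with an estimated correlation). The mitotic call was lost with genes at or above the median level (adjusted p = 0.144), without a trend (0.0721) and without the third control array (0.224).

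Of 24 p53 targets 4 rose and none fell (13 rose when adjusted over the list alone; camera, adjusted p = 6.27e-08; adjusted p = 0.0567 with an estimated correlation). These were TP53INP1, which rose by 0.22, the ribonucleotide reductase subunit RRM2B, by 0.16, CDKN1A, the CDK inhibitor p21, by 0.15, and the DNA repair gene XPC, by 0.12. Among 13 CDK inhibitors, D cyclins and partners, CDKN2B rose by 0.25, CDKN1A by 0.15 and CCND3 by 0.14, while MYC fell by 0.19 and CCND1 by 0.14. The same 3 were higher and 2 lower when adjusted over the list alone (camera, adjusted p = 0.718). Of 23 targets of YAP and TAZ 3 rose, CCN1 by 0.24, LATS2 by 0.15 and F3 by 0.15. The list held 7 higher and 2 lower when adjusted over the list alone (camera, adjusted p = 0.000781; adjusted p = 0.0716 with an estimated correlation). Of 18 histone genes, H1-2 rose by 0.17 and H2BC12 by 0.09. Both belong to families of close copies, and H1-2 was read by 1 probe set, of the _x_at type. The list held 7 higher when adjusted over the list alone (camera, adjusted p = 5.15e-05; adjusted p = 0.0497 with an estimated correlation).

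Genes of sterol synthesis and of the unfolded protein response were lower in the arrays labelled overexpression. Of 23 genes of cholesterol and fatty acid synthesis 6 fell and SREBF1, a transcription factor of lipid synthesis, rose by 0.15. In that list 10 fell and 1 rose when adjusted over the list alone (camera, adjusted p = 1.69e-09; adjusted p = 0.0497 with an estimated correlation). MSMO1 fell by 0.36, the sterol enzymes SQLE and DHCR7 by 0.24 each, and the fatty acid elongase ELOVL6 by 0.18. Of 23 genes of the unfolded protein response 5 fell, led by the chaperone HSPA5, by 0.20, and PDIA3, by 0.16, followed by SDF2L1, by 0.12, and PDIA4, by 0.11. In that list 11 fell and 1 rose when adjusted over the list alone (camera, adjusted p = 6.73e-09; adjusted p = 0.0497 with an estimated correlation). Of 16 heat shock genes DNAJB1 fell by 0.15 and HSPB1, read by 1 probe set of the _x_at type, by 0.11. In that list 3 fell and 1 rose when adjusted over the list alone (camera, adjusted p = 0.000126, and adjusted p = 0.0881 with an estimated correlation).

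Of 24 amino acid genes tied to ATF4, CTH, which makes cysteine, fell by 0.24, SHMT2 by 0.13 and CEBPB by 0.12, while the cystine transporter SLC7A11, which is also on the NRF2 list, rose by 0.13. In that list 10 fell and 2 rose when adjusted over the list alone (camera, adjusted p = 0.000106; adjusted p = 0.113 with an estimated correlation). Of 28 genes of ribosome biogenesis and MYC targets, the nucleolar genes FBL and NOP56 fell by 0.13 each and NOLC1 by 0.11. In that list 4 fell when adjusted over the list alone (camera, adjusted p = 2.2e-08; adjusted p = 0.0678 with an estimated correlation). None of 35 cytosolic ribosomal protein genes was called by either adjustment, with RPL13 at -0.07 and RPS2 at -0.09 (camera, adjusted p = 0.0903). The list was called as lower with the mean of all probe sets (adjusted p = 0.0333) and without the second overexpression array (0.0450) or the second control array (0.0436).

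**Figure D3:**
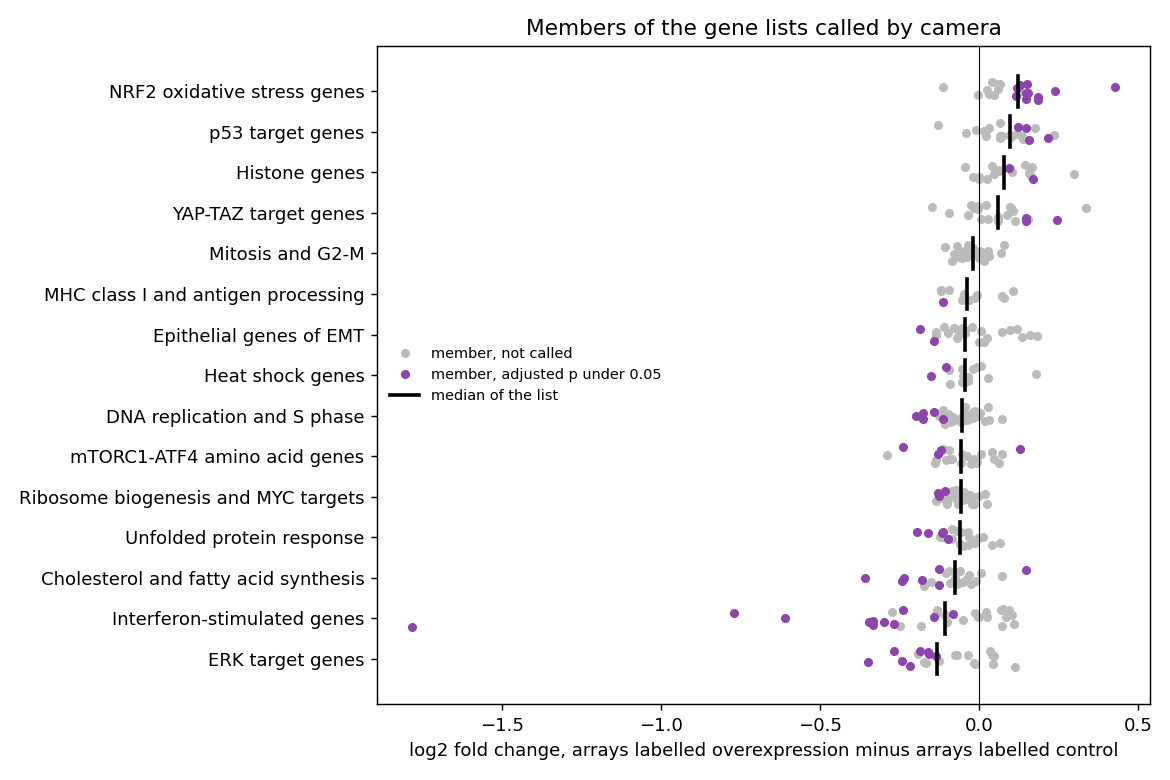
Log2 fold change, arrays labelled overexpression minus arrays labelled control (horizontal axis), of the measured members of the 15 gene lists called by camera (vertical axis), with 1 point per gene, called genes in purple and a black line at the median of each list. Medians ran from -0.13 for ERK targets to 0.12 for NRF2 genes, and most single members lay within 0.5 of 0, the exceptions being IFI27, IFI6 and IFITM1.

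In the PI3K-Akt-mTOR pathway, a growth and survival route, 2 of 37 measured components rose in the arrays labelled overexpression, the adaptor IRS2 by 0.13 and the kinase GSK3B by 0.11, with the same 2 when adjusted over the list alone. The list was not called (camera, adjusted p = 0.419), and AKT1 at 0.03, AKT2 at 0.05 and MTOR at 0.04 were not called. Of 21 FOXO targets IRS2 rose by 0.13 and TXNIP, an inhibitor of thioredoxin, fell by 0.16 (2 rose and 3 fell when adjusted over the list alone; camera, adjusted p = 0.718). In the CADM and nectin adhesion family of 12 genes, NECTIN4 rose by 0.26 and CADM1 fell, with the same pair when adjusted over the list alone (camera, adjusted p = 0.718). None of 14 cytoplasmic partners of CADM1 was called by either adjustment, with EPB41L1 at 0.18 and PARD3 at 0.14 (camera, adjusted p = 0.906). All 4 EPB41L1 probe sets had that sign. One of the dimmer ones, 11721168_a_at, gave 0.32 and was called on its own (limma, adjusted p = 0.0301 over all probe sets). Only 2 of the 4 PARD3 probe sets had the sign given.

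Adhesion genes included 3 that fell among 28: the integrin subunits ITGA2, by 0.32, and ITGA6, by 0.12, and the tetraspanin CD9, by 0.15, for which 7 of 9 probe sets had that sign. Of these 28, 4 fell and 1 rose when adjusted over the list alone (camera, adjusted p = 0.259). Of 24 epithelial genes the desmosome gene DSP fell by 0.18 and the transcription factor ELF3 by 0.14, and 4 fell when adjusted over the list alone. The list was called as lower (camera, adjusted p = 0.0257; adjusted p = 0.124 with an estimated correlation). That call was lost without a trend (adjusted p = 0.149) and without the third overexpression array (0.0553) or the third control array (0.0615). Of 25 mesenchymal genes ACTA2, smooth muscle actin, rose by 0.26 and SNAI2 by 0.18, while TGFBI fell by 0.22. In that list 2 rose and 2 fell when adjusted over the list alone (camera, adjusted p = 0.718). For ACTA2, 2 of 3 probe sets had that sign. Among 24 matrix proteases and inhibitors PLAU, the urokinase gene, rose by 0.22 and SERPINE2 fell by 0.16, with 5 of its 6 probe sets of that sign. In that list 1 rose and 4 fell when adjusted over the list alone (camera, adjusted p = 0.308).

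Among signalling lists without a call, 21 TGF-beta targets included CDKN2B and ID2, which rose by 0.25 and 0.18, and TGFBI and ID1, which fell by 0.22 and 0.10. These were the same 2 and 2 when adjusted over the list alone (camera, adjusted p = 0.542). Of 17 WNT targets MYC and CCND1 fell (3 fell when adjusted over the list alone; camera, adjusted p = 0.16). Of 25 NF-kB genes and cytokines IL1A rose by 0.34 from a low level of 4.87, and TNFAIP2 fell by 0.14 with 4 of 5 probe sets of that sign. The same pair passed when adjusted over the list alone (camera, adjusted p = 0.795). Of 31 genes of glycolysis and the hypoxia response NDRG1 rose by 0.20, the glucose transporter SLC2A1 by 0.16 and ADM by 0.14, while ANGPTL4 fell by 0.27. In that list 3 rose and 5 fell when adjusted over the list alone (camera, adjusted p = 0.337). None of 21 apoptosis promoting genes and none of 9 inhibiting genes was called by either adjustment, with BBC3 at 0.14, BID at -0.10, CFLAR at 0.08 and MCL1 at -0.04 (camera, adjusted p = 0.487 and 0.835). Of 30 autophagy and lysosome genes the cargo receptor SQSTM1 rose by 0.12, and it alone passed when adjusted over the list alone (camera, adjusted p = 0.16). None of 29 oxidative phosphorylation genes was called by either, with NDUFB8 at 0.07 and NDUFB5 at 0.10 (camera, adjusted p = 0.209).

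Markers of other cell types did not move as groups. The endothelial gene CDH5 fell by 0.27, at levels of 6.50 and 6.77. It was 1 of 11 endothelial markers by either adjustment and the only called gene among the cell type and housekeeping lists. In the ovarian list MSLN gave 0.10 and FOLR1 -0.08 (1 rose and 1 fell when adjusted over the list alone). None of the fibroblast, blood and other lineage markers was called by either adjustment, with DES at -0.21, PDGFRA at 0.15, CD3E at -0.12, CD14 at -0.13, ALB at 0.18 and CDX1 at 0.14 (camera, adjusted p = 0.943 for each of these 5 cell type lists). Housekeeping genes gave 0 calls over all genes and 1 lower when adjusted over the list alone, with TFRC and PPIA at -0.07 each (camera, adjusted p = 0.13).

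Of the 88 called genes named by the rule besides CADM1, 21 moved by over 1.5 times in log2 fold change under some setting. With the mean of all probe sets, which weighs dim and bright ones alike, ABCA1 gave 0.30, KRTAP12-2 0.28, AHRR 0.18 and HSPA5 -0.11, still called. Under that setting ACTA2 at 0.07, CD9 at -0.06, DSP at -0.11, LATS2 at 0.10, NDRG1 at 0.13, RAP1A at 0.05, RRM2 at -0.03, RRM2B at 0.09 and TMEM67 at -0.02 lost their calls. With 64 added on the linear scale UBE2L6 gave -0.29, KRTAP12-2 0.24, TMEM67 -0.23, TTC3P1 0.19, CYP4F11 0.18, DUSP5 -0.18, HHIPL2 0.15 and IL1A 0.12, still called, while CDH5 at -0.16 and NECTIN4 at 0.14 lost their calls.

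Where no member of a list was called by limma, the members at an unadjusted p under 0.05 numbered 8 for mitosis, 3 for oxidative phosphorylation, and 2 each for CADM1 partners, apoptosis promoting genes, metallothioneins and ribosomal proteins. They numbered 0 for apoptosis inhibiting genes and blood markers, 1 each for fibroblast and other lineage markers, 2 for ovarian markers and 5 for housekeeping genes.

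Camera called 15 of 33 lists, 4 higher and 11 lower in the arrays labelled overexpression. With an estimated correlation it called 7, all but NRF2 at the same adjusted p of 0.0497. The median, mean and test differed in sign for the blood markers and for 5 of the 33 lists, all without a call, such as the CADM and nectin family, with a median of 0.03, a mean of -0.13 and a test direction of lower. The 3' minus 5' signal of the GAPDH control, a sign of RNA quality, was -0.13 ± 0.0084 (SD, n = 3) in the arrays labelled overexpression and -0.15 ± 0.0036 (SD, n = 3) in those labelled control, without overlap, while that of ACTB overlapped. Among the 9 other splits of the 6 arrays into groups of 3, up to 8 lists were called.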

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

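The tests of the CADM1 probe set, of probe set choice, single arrays and the construct for the interferon-stimulated genes, and of RNA degradation were chosen after the result was seen. Outside the genes compared, 4305 probe sets named several genes or none, and of these 21 were higher and 56 lower in the arrays labelled overexpression (limma, adjusted over all probe sets), with log2 fold changes from -0.47 to 0.48.

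CADM1 probe set 11728805_a_at was lower in each array labelled overexpression. A CADM1 transcript lowered along its whole length stays open: the other CADM1 probe sets above the median level gave a lowest 95% bound of -0.071, but without detection calls it is not known whether they detect CADM1. An exchange of the labels of the 2 groups may account for it, with 6 of 6 arrays on the wrong side for their label, but that value restates the pattern. Probe set 11757557_s_at ran the way the labels say, at 0.17 with an unadjusted 95% interval of 0.07 to 0.27, but was not called (limma, adjusted p = 0.0975). It had the highest value of the other CADM1 probe sets and was picked after the values were seen. The rest lay between -0.06 and 0.04. Its groups did not overlap, as was so for 18.3% of all genes, so it does not decide whether the labels were exchanged. A probe set that does not report CADM1 cannot be told apart from these explanations, since 1 CADM1 probe set was called and no probe sequences were used here. A response of the cells' own CADM1 transcript to the introduced one stays open and was not tested.

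Interferon-stimulated genes were lower in the arrays labelled overexpression. A single array as the cause is argued against, as the highest camera adjusted p without 1 array was 1.25e-11. For the choice of 1 probe set per gene, 6 of the 8 called members with several probe sets had 1 sign in all of them, short of the 80% set as the bound; the list's adjusted p of 5.78e-11 with the mean of all probe sets and the 0 called probe sets of opposite sign were brought in after that miss, and argue against this choice as the whole cause. The controls were mock cells, so a response to the procedure alone may lie in both groups. A response that raises these genes in the construct arrays alone would need exchanged labels, since as labelled these arrays had the lower signal. All 11 called members were higher in the arrays with the higher CADM1 signal. This restates both differences and decides nothing, and no test was made within a label. The biological explanation given by the design, a CADM1 effect, stays open.

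Gene lists shifted by small amounts. A bias that follows the expression level is argued against for 14 of the 15 called lists, whose medians lay outside the 95% range of 10000 random lists matched on level, the exception being MHC class I. A difference in RNA degradation cannot be told apart from the grouping: the 3' minus 5' control signal differed by at most 0.014, for GAPDH, but the groups did not overlap there (-0.13 ± 0.0084 against -0.15 ± 0.0036, SD, n = 3 each), and called lists shifted by as little as -0.019. For chance, the 10 splits of the 6 arrays are too few for a share under 0.05: the real split gave 15 lists against at most 8 in the others, 392 genes against 0, and 2 genes at least 2-fold against 0, each reached by 1 split, the real one. The other splits mix the labels unevenly, so part of the labelled difference stays between their groups and part adds to the spread within them. The latter works against calling genes there. The 8 lists called in another split may come from that remainder or from a preset correlation too low for these arrays. The estimated correlation left 7 lists called, all but NRF2 at the same adjusted p of 0.0497 (camera), just under the bound.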

How the results depend on the processing

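CADM1 kept its direction and its call in all settings that keep 1 value per gene, from -1.90 with 64 added to -2.14 among the fits that left out 1 array (lowest -2.14, highest -2.10), and at -0.32 with the mean of all probe sets (adjusted p = 0.00131). The other CADM1 probe sets gave 0.038 (11728806_a_at), 0.038 (11741375_a_at), 0.17 (11757557_s_at), -0.0061 (11754473_a_at) and -0.061 (11762680_s_at); the cause was not tested. The 392 called genes became 11 without a mean-variance trend, 735 probe sets with every probe set on its own (49395 in the table against 18118 genes), 20 by a plain t-test after Benjamini-Hochberg, which uses each gene's own spread alone, and 6 by a plain t-test at p under 0.05 with a 1.5-fold change, against 6 called by limma with that fold change. The fits that left out 1 array called 116 to 379 genes with fewer arrays, and those without overexpression array 1 or 2 and control array 1 or 2 gave 116, 226, 142 and 189. The other settings gave 329 to 563. With the replicate number as a block 172 genes were called, all among the 392, and 15 lists; same-numbered arrays correlated at 0.129, -0.071 and -0.073 in their deviations from the group mean, so the numbers do not pair the arrays. Genes at least 2-fold changed stayed at 2, except 1 with the mean of all probe sets, where CADM1 is averaged with probe sets that were not called, and 3 probe sets with every probe set on its own. The 15 lists became 7 with an estimated correlation and 14 with fry, 13 of them shared, and 12 without a trend; leaving out 1 array gave 13 to 15 and the other settings 13 to 16. Camera called 2 further lists under some alternative, cytosolic ribosomal proteins and metallothioneins, and fry called the CADM and nectin family. Of 88 called genes named by the rule besides CADM1, 9 kept their call in every other limma fit at the gene level, and 12 of 15 lists kept theirs over the camera settings at the preset correlation. In these fits no named gene or list that was called turned direction. Over single probe sets, 247 of the 303 called genes with several had 1 sign in all of them. TMEM67 had a called probe set of the opposite sign, at 0.41, which averaged a dim 3.09. Signal over background could not be set from these values, so how far dim genes are limited is open.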

Other observations

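Targets of the aryl hydrocarbon receptor, which senses small aromatic molecules, included 2 called genes that no list held: the cytochrome CYP1B1 rose by 0.16 ± 0.026 (SE; limma, adjusted p = 0.00414) and the aldehyde dehydrogenase ALDH3A1 by 0.20 ± 0.030 (SE; limma, adjusted p = 0.00284) in the arrays labelled overexpression, with no overlap between the groups. CYP1A1, a classical target of the receptor, gave -0.09 at a level of 5.90, and TIPARP 0.08, and neither was called. Among the 9 measured members of a list of LXR targets besides ABCA1, the highest were ABCG1 at 0.19 and MYLIP at 0.16, without a call (limma, adjusted p = 0.156 and 0.0807). The lowest was NR1H3 at -0.05.

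The 2 hypotheses were drawn from genes seen to rise, and their lists, without those genes, were written before the members were looked at. After AHRR and NQO1 rose, a list of 6 other targets of the aryl hydrocarbon receptor was tested. Camera, from limma, gave an adjusted p = 0.000234 over the 2 lists (0.000117 before adjustment), with a mean log2 fold change of 0.10, 95% interval -0.01 to 0.20. That value goes with a joint rise, although the interval over the genes includes 0. Both lists were tested at the preset correlation of 0.01 alone, not with an estimated one, and the intervals treat the genes as independent. NFE2L2, on that list, encodes NRF2 itself and gave 0.09 without a call (limma, adjusted p = 0.263). ALDH3A1 is also tied to NRF2, so the responses of NRF2 and of the aryl hydrocarbon receptor were not separated. After ABCA1 rose and sterol synthesis genes fell, a list of 9 other measured targets of LXR was tested. That list was a selection and left out SREBF1, which was called higher on the cholesterol and fatty acid synthesis list. Camera, from limma, gave an adjusted p = 0.0810 (0.0810 before adjustment), with a mean log2 fold change of 0.06, 95% interval -0.0015 to 0.12, which neither shows nor excludes a joint rise.

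RAP1A probe set 11762533_a_at read 14.22 ± 0.010 (SD, n = 3) in the arrays labelled overexpression and 13.83 ± 0.033 (SD, n = 3) in those labelled control, while its other probe sets read between 8.08 and 8.89.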
